A study of Mus musculus with 6 samples.

How the data were processed

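Libraries were made from 3 wild type and 3 STIM1 knockout mice of 1 year, from the microdissected Purkinje neuron and molecular layers of the cerebellum. Per the labels' protocols, TRIzol total RNA (about 500 ng with an average RIN of 8.2) went into a TruSeq mRNA kit and was sequenced on an Illumina HiSeq 2500 as single reads of 50 bases. Per the submitters' processing notes, TopHat, HTSeq 0.9.1, DESeq and edgeR were used with the mouse build GRCm38 (mm10). Whether the kit marks strand, which strand setting was used in counting and which annotation was counted are not given in the sources used here.

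The deposited per-sample files hold whole-number counts per gene symbol that the authors made from aligned reads, with 5 HTSeq rows that name no gene. Those rows were left out of library sizes and tests. Reads assigned to no gene were 98.76% to 98.84% of the uniquely aligned reads per library, reads ambiguous between genes 0.00416% to 0.00492%, and rows for unaligned and low-quality reads were 0. The authors also deposited a DESeq table with normalised mean signal per genotype, a ratio (fold change, KO over WT) and a p-value, and an edgeR table with a log2 ratio (WT over KO), a log2 CPM and a p-value. These tables were used for description alone, and 1 column of the DESeq table with non-numeric cells was not used here.

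Differences were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM factors of 0.954 to 1.04, filterByExpr by genotype with a minimum count of 10, Benjamini-Hochberg adjusted p under 0.05), on all 6 libraries with no covariate. The standard error of a log2 fold change is the one implied by the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes. A count of 0 allows up to 3 counts, or 3.92 to 4.64 CPM on library sizes without the TMM scaling. The titles number the replicates of each genotype from 1 to 3, and the series text calls them biological replicates. Gene lists (20 lists of pathways and 15 of cell type markers) were tested with camera in limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, where at least 3 members were tested, and with fry; 24 lists were tested and 11 were not. Samples, tests, lists and most alternative settings were fixed before the data were examined. The named genes are Stim1, the 5 genes of lowest p per direction where fewer than 5 pass (passing over symbols of predicted genes), the passing members of each list or else the 2 with the lowest p, and the sex-linked genes; 6 of the 64 genes that the rule takes from the tested set are not reported here. Inf2, Ctsa and the genes opposite abundant transcripts were chosen after their values were seen.

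Gene positions and exon overlaps come from GENCODE mouse release M21 on GRCm38, in which 23376 of 24421 symbols (95.7%) were matched. A gene was said to have an opposite-strand partner where at least 50 bases of exon are shared. The lists of mitochondrially encoded RNAs, endothelial and erythrocyte markers had 0 tested genes.

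The tests were checked on simulated counts with the means and library sizes of the 5320 tested genes, 200 of them changed, in 5 simulations. For KO against WT, 58% of 2-fold changes and 88.2% of 4-fold changes were recovered, with 27.3% of 2-fold changes among genes below the median count. These shares hold for 200 changed genes. The simulated libraries lacked the structure by replicate number described below, so the shares may differ in the real libraries. A presynaptic list shifted by -0.5 on the log2 scale was recovered in 20 of 20 simulations. The simulated genes varied independently of each other, while the correlation estimated for this list was 0.043. The shift was also larger than the observed median of -0.19, so the simulation does not check the list calls below. Alternatives were DESeq2 1.42.0, the edgeR exact test, limma-voom, other normalisations and filters, other thresholds, a replicate block, leaving out each library in turn and, chosen after the data were examined, other library sizes, genes with or without an opposite-strand overlap and the libraries without Y-linked counts.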

Results

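RNA was sequenced from microdissected cerebellar tissue of 1 year old mice, taken as the Purkinje neuron layer together with the molecular layer, from 3 wild type (WT) and 3 STIM1 knockout (KO) animals. STIM1 is the endoplasmic reticulum calcium sensor that opens Orai channels in the plasma membrane when the store empties. The comparison of the genotypes asks which transcripts differ in this tissue between mice labelled wild type and STIM1 knockout. The 6 libraries held from 645994 to 764839 counts in 24421 genes, and 16540 genes had a count in any library. Those gene counts made up 1.16% to 1.23% of the uniquely aligned reads, and 98.8% were assigned to no gene in every library. The lowest library, KO replicate 3, had 1.155% in genes (Wilson 95% interval 1.152% to 1.158%), and the highest, WT replicate 1, 1.232% (1.229% to 1.235%). The median count of a tested gene was 24 to 31 per library, so single genes carried a wide counting error. Intervals of this kind and limits for a count of 0 cover counting error only. Pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 2.34, and all 6 were kept as separate replicates.

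Stim1 (chromosome 7, 102267806 to 102437319, plus strand, GRCm38) was read at very low depth. It had 7, 21 and 3 counts in WT replicates 1 to 3 and 4, 3 and 2 counts in KO replicates 1 to 3. The mean was 15.5 ± 14.4 CPM (SD, n = 3) in WT and 4.24 ± 0.964 CPM (SD, n = 3) in KO, a log2 ratio of -1.87. An exact two-sided permutation test gave p = 0.3, and the smallest p that 3 against 3 allows is 0.1. Without WT replicate 2 the log2 ratio was -0.79. The counts lay below the filter of the main test, and the labels name neither the exons removed nor the cells in which they are removed, so the whole-gene count is a weak check of the genotype. It is uncertain too which strand was counted, and with it whether these counts are Stim1 mRNA. Its relatives were as low. Stim2 had 5, 2 and 2 counts in WT and 1, 1 and 4 in KO, and Orai2, a pore subunit of the store-operated channel, had 7, 11 and 12 counts in WT and 11, 8 and 7 in KO. Orai1 had at most 3 counts in any library. Orai3 had 3, 3 and 5 counts in WT and 0, 0 and 1 in KO, with an exact permutation p = 0.1, the smallest possible.

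No single gene passed the comparison of KO with WT. As for Stim1, the sources do not give for any gene which strand was counted, and the strand checks below go with the opposite one. The values below, and the absence of calls, may therefore not describe the mRNA of the genes named. Among the 5320 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.917. The genes nearest to a difference on the lower side were Pvalb, which encodes the calcium buffer parvalbumin of Purkinje cells and molecular layer interneurons, and Vamp1, a vesicle SNARE. Pvalb (chromosome 15) averaged 196 ± 22.8 CPM (SD, n = 3) in WT and 119 ± 11.9 CPM (SD, n = 3) in KO, a log2 fold change of -0.73 with a standard error of 0.17, and every KO library lay below every WT library. Itpr1, the IP3 receptor that releases calcium from the endoplasmic reticulum of Purkinje cells, averaged 1729 ± 248 CPM in WT and 1253 ± 111 CPM in KO (SD, n = 3 each), a log2 fold change of -0.47 with a standard error of 0.14 and an adjusted p of 0.917. At an unadjusted p under 0.05 there were 246 genes, 84 higher and 162 lower in KO, where 266 are expected by chance. The groups did not overlap for 568 genes, 10.7% of those tested, where chance gives 10%. The DESeq2 Wald test and limma-voom also called 0 genes. With no filter on low counts the edgeR test called 6, described with the other settings.

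The 5 genes with the lowest p in each direction are named although none passed. On the lower side Vamp1 had a log2 fold change of -1.33 (SE 0.33), Ddx17, an RNA helicase, -0.99 (SE 0.26), Bcar1, an adhesion signalling scaffold, -1.87 (SE 0.52), and Hspa12a, an HSP70 relative, -1.07 (SE 0.30). On the higher side Gtf3c2, a subunit of transcription factor IIIC, had a log2 fold change of 1.86 (SE 0.42) on 3, 8 and 4 counts in WT and 26, 15 and 16 in KO. Erdr1 had 0, 0 and 84 counts in WT and 113, 226 and 88 in KO, so WT replicates 1 and 2 set it apart. Without WT replicate 3 it passed with an edgeR adjusted p of 1.38e-05. Insr, the insulin receptor, had a log2 fold change of 1.36 (SE 0.43), Ptrh2, a peptidyl-tRNA hydrolase, 0.78 (SE 0.25), and Pcdha2, a clustered protocadherin, 0.86 (SE 0.28).

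**Figure D1:**
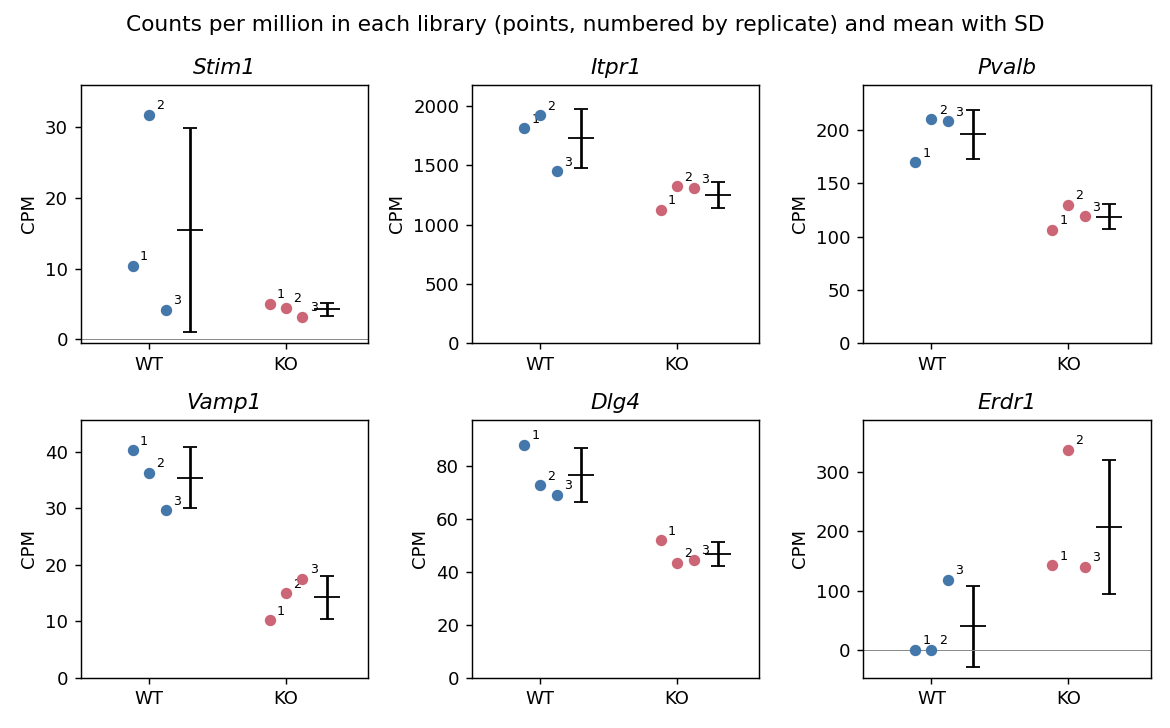
CPM (vertical axes, linear) of 6 genes in each library, with points numbered by replicate and a bar for the mean ± SD of 3 libraries per genotype. Pvalb, Vamp1 and Dlg4 lie lower in each KO library than in each WT library, Stim1 is set by WT replicate 2 with 21 counts, and Erdr1 is at 0 in WT replicates 1 and 2; none of the 6 passed the edgeR test at an adjusted p under 0.05.

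With a preset correlation 2 lists of synaptic genes were lower in the knockout. Of the 24 lists with at least 3 tested members, 2 passed limma camera with a preset correlation, and both were lower in KO. The camera direction was lower in KO for 21 of the 24, so that direction was not particular to synaptic genes. Of 36 tested genes of presynaptic vesicle release 28 were lower and 8 higher, with a median log2 fold change of -0.19 and an adjusted p of 0.00525. Of 22 tested glutamate receptor and postsynaptic density genes 17 were lower and 5 higher, with a median of -0.15 and an adjusted p of 0.0325. Neither call held with an estimated correlation (adjusted p = 0.439 for both), and neither held in fry (adjusted p = 0.347 for both). In the presynaptic list the examples were Vamp1 and the synaptotagmin Syt11 (-0.47, SE 0.17), and 1 member, Vamp1, passed when adjusted over the list alone (adjusted p 0.0262). Adjustment over a list alone does not correct for the number of lists. Over all lists 4 members passed it, and 0 passed the main test. In the postsynaptic list they were Dlg4, which encodes PSD-95 (-0.71, SE 0.22), and the AMPA receptor subunit Gria1 (-0.29, SE 0.14), and 0 members passed when adjusted over the list alone. The presynaptic call ended without KO replicate 3 (0.204), without both libraries that hold Y-linked counts (0.274), with a CPM filter (0.162) and among genes with no opposite-strand overlap (0.546). The postsynaptic call ended without WT replicate 1 (0.101), WT replicate 2 (0.208), WT replicate 3 (0.0569), KO replicate 2 (0.21) or KO replicate 3 (0.0747), without both libraries that hold Y-linked counts (0.0713), with the CPM filter (0.535) and among genes with no opposite-strand overlap (0.546). Leaving out each library, the medians stayed below 0, from -0.29 to -0.16 for the presynaptic and -0.27 to -0.13 for the postsynaptic list.

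Calcium and Purkinje cell lists had medians below 0 without passing in the main test, though 3 of them passed in other settings. The list of calcium binding proteins and effectors had 11 of 15 tested members lower and a median of -0.11 (camera adjusted p 0.0632, 0.0414 and 0.0353 with the 2 other library sizes, 0.439 with an estimated correlation and 0.546 among genes with no opposite-strand overlap), while fry's test for changes in either direction gave an adjusted p of 0.0226. Pvalb was the only member to pass when adjusted over the list alone (0.00598). Purkinje cell markers had 12 of 16 members lower and a median of -0.22 (adjusted p 0.08, 0.0411 without KO replicate 2 and 0.526 with an estimated correlation). Leaving out each library, the Purkinje median ranged from -0.30 to -0.095. Of the 16, 8 share exon with a gene on the other strand, and among genes with no such overlap the median was -0.14 (adjusted p 0.646). When adjusted over the list alone Itpr1 passed (0.0492), and Gng13, a G protein gamma subunit, lay at -0.44 (SE 0.20). The mGluR1 and IP3 pathway had a median of -0.034 (camera adjusted p 0.233, and 0.594 with an estimated correlation). The median was -0.27 without KO replicate 2 (adjusted p 0.0293) and 0.022 without KO replicate 1. After Itpr1 the lowest p of this list belonged to Atp2a2, the SERCA2 pump that refills the store, at -0.32 (SE 0.17). All 4 tested members of the store-operated entry list were lower, with a median of -0.31 (adjusted p 0.193), among them Atp2a2 and Sept7 (-0.31, SE 0.17); the median was -0.13 without KO replicate 1 and 0.048 among genes with no opposite-strand overlap.

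Astrocyte and Bergmann glia markers had medians below 0 without passing with all 6 libraries. Astrocyte markers had 8 of 11 members lower and a median of -0.26 (camera adjusted p 0.0632, 0.0346 without WT replicate 3 and 0.51 with an estimated correlation). Leaving out each library, this median ranged from -0.34 to -0.14. Among them S100b, a glial calcium binding protein, lay at -0.74 (SE 0.22) and passed when adjusted over the list alone (0.0443), and Aldh1l1 lay at -0.95 (SE 0.39). Bergmann glia markers had a median of -0.29 (adjusted p 0.168), with the glutamate transporter Slc1a3 at -0.31 (SE 0.16) and Sept4 at -0.42 (SE 0.24). Granule cell markers had 6 members higher and 7 lower and an adjusted p of 0.993, with Gabrd, the extrasynaptic GABA-A receptor delta subunit, at 0.69 (SE 0.27) and Gabra6 at -0.56 (SE 0.46). Molecular layer interneuron markers had 3 tested members with a median of -0.19 (adjusted p 0.194), with Tfap2b at -0.77 (SE 0.31) and Kit at -0.19 (SE 0.26). The interneuron median ranged from -0.47 to -0.099 leaving out each library. Oligodendrocyte markers had a median of -0.060 (adjusted p 0.724), with Trf at -0.39 (SE 0.30) and Cnp at 0.11 (SE 0.33).

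The remaining lists gave no call with all 6 libraries. Sodium, potassium and HCN channels had a median of -0.10 (adjusted p 0.233), with Scn1a at -0.60 (SE 0.27), and voltage-gated calcium channels a median of -0.050 (0.993), with Cacng2 at -0.40 (SE 0.23) and Cacna1d at 0.44 (SE 0.39). GABA and glycine signalling had a median of -0.11 (0.233), with Gabrd as above. Synaptic adhesion and guidance genes had a median of -0.029 (0.233), with Robo2 at -0.79 (SE 0.26) and Nrcam at -0.84 (SE 0.30). Proteasome subunits had a median of -0.18 (0.193), with Psma4 at -0.84 (SE 0.29) and Psmc1 at -0.75 (SE 0.26). Heat shock chaperones had a median of -0.10 (0.193, 0.0293 without KO replicate 2 and 0.51 with an estimated correlation), with Hspa8 at -0.36 (SE 0.18) and Fkbp4 at -0.41 (SE 0.23). Leaving out each library, the chaperone median ranged from -0.31 to -0.0093. Nuclear genes of oxidative phosphorylation had a median of -0.13 (0.35), with Atp5b at -0.48 (SE 0.15) and Sdha at -0.66 (SE 0.21), and ribosomal proteins -0.064 (0.584), with Rpl11 at -0.49 (SE 0.26). Immediate early genes had 4 of 4 tested members higher with a median of 0.10 (0.397), among them Fosl1 at 0.21 (SE 0.15) and Jund at 0.10 (SE 0.13). The lists of the unfolded protein response (median 0.020; Sel1l -0.56, Hspa5 -0.22), glial reactivity (0.028; Gfap -0.16, Apoe 0.028), histone lysine enzymes (-0.0074; Kmt2c -0.81, Setd7 -0.30) and cholesterol synthesis (0.040; Hmgcs1 -0.54, Fdft1 0.18) each had an adjusted p of 0.993. The lists with under 3 tested members were not tested, and among their tested members Nefh had a log2 fold change of -0.16, Gpr17 0.15, Ptgds 0.19, Tagln 0.22, Prlr 0.23, Des 0.25 and Eomes 0.42.

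**Figure D2:**
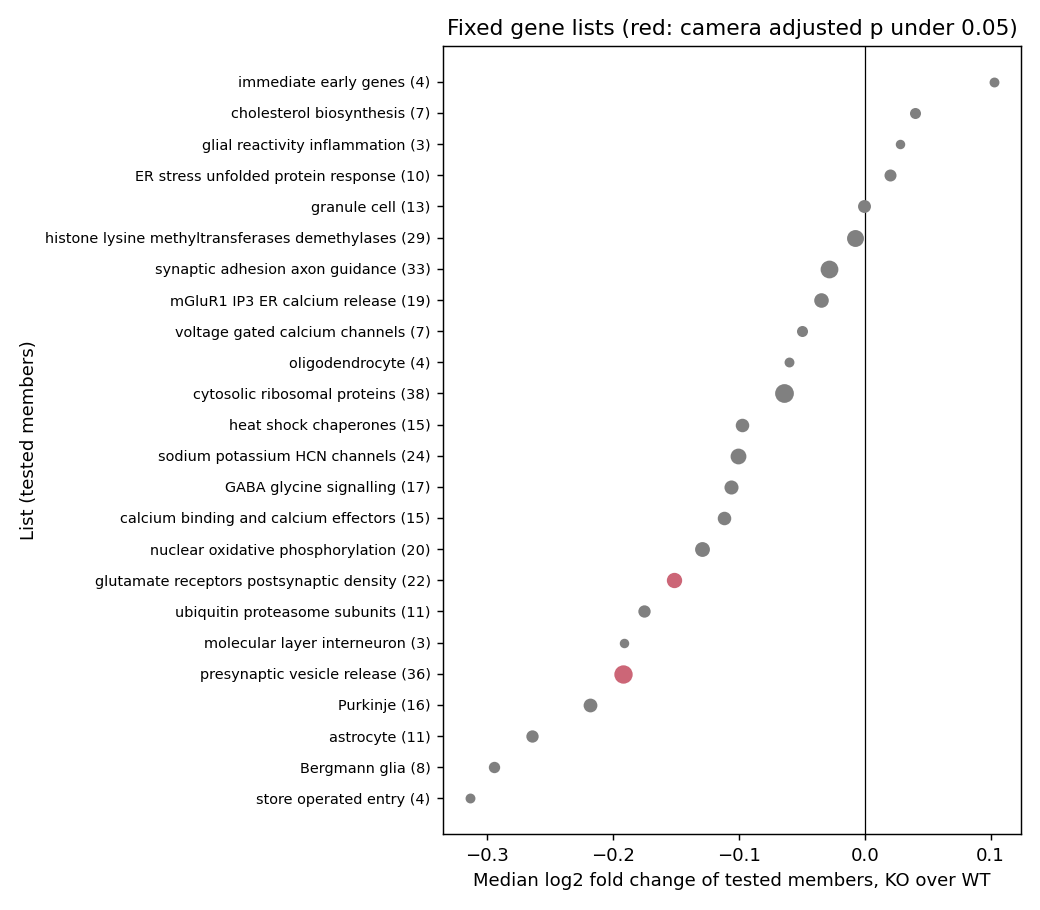
Median log2 fold change, KO over WT, of the tested members of the 24 lists that were tested (horizontal axis, linear), with the number of members in brackets and as point size. The presynaptic list (-0.19) and the glutamate receptor list (-0.15) are the 2 with a camera adjusted p under 0.05, neither of which passed with an estimated correlation, and lists without a call, such as Bergmann glia (-0.29), lie further from 0.

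Markers of sex and of opposite strands were read in every library as checks. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 28 counts together in WT replicate 3, 14 in KO replicate 3 and 0 in the other libraries, so that 1 library of each genotype stood apart. Tsix, which is transcribed opposite to Xist, had 3053, 2987 and 2 counts in WT and 3265, 3019 and 1 in KO, and Xist 139, 79 and 10 in WT and 100, 108 and 4 in KO. Of the 58 genes reported under the fixed rule, 22 share at least 50 bases of exon with a gene on the other strand, among them Itpr1 and Hspa12a. Fosl1 shares 1163 such bases, Jund 877 and Fdft1 774. Tested genes with no such overlap had 28 higher and 119 lower at an unadjusted p under 0.05, and genes with one had 46 higher and 40 lower. That contrast depends on normalising the classes together: normalised alone, 42.0% of such genes without an overlap and 37.4% of those with one were higher.

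The authors' deposited tables compared the same 6 libraries. The authors' deposited DESeq table held 307 genes at an unadjusted p under 0.05, 123 higher and 184 lower in KO, and the authors' deposited edgeR table had 464 such genes, 187 higher and 277 lower. Of the 246 genes at that level here, 206 were among those of the authors' deposited edgeR table and 144 among those of the authors' deposited DESeq table. After a Benjamini-Hochberg adjustment computed here, the lowest p was 0.399 in the authors' deposited DESeq table and 0.237 in the authors' deposited edgeR table. The authors' deposited DESeq table gave Stim1 a fold of 0.279 in KO over WT with p = 0.202, and the authors' deposited edgeR table a log2 ratio of WT over KO of 1.79 with p = 0.0172.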

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

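Nearly all uniquely aligned reads lay outside the main measurement: on average 98.8% were assigned to no gene. The counts give only their total, so what these reads are cannot be seen. The tests of build and of genomic DNA were chosen after the result was seen. The test of strand had been written before; a second form of it without the requirement below was run first, and both are given. In pairs of a listed gene and a tested gene that shares exon on the other strand, the opposite gene held more counts in 80.6% of 67 pairs (exact 95% interval 69.1% to 89.2%). Requiring the opposite gene to be tested favours it, and with either gene at a mean count of 10 or more the share was 63.5% of 85 pairs (52.4% to 73.7%), while the 70% set in advance was for tested partners. These values go with counting on the opposite strand, as do 74.4% of gene counts in genes with an opposite partner (28.2% of exonic bases). So does Tsix at 22 to 37.8 times Xist in the libraries without Y-linked counts. Reads that kept no strand would fall in a transcript's own gene as often as opposite it. The excess of Tsix and the 98.8% in no gene argue against such reads. The labels do not say whether the kit marks strand, so opposite-strand counting stays a hypothesis for single genes. Gene models placed on another genome build would not favour such partners, yet counts per kilobase of exon were 7.42 times higher (bootstrap 95% interval 5.90 to 9.21) in genes with an opposite partner than in genes without. Genomic DNA would give Tsix in every library, yet its mean CPM was 2009 times higher in the 4 libraries without Y-linked counts than in the 2 with them. No biological explanation was tested. The share of reads in genes was 1.21% ± 0.0265 in WT and 1.19% ± 0.0345 in KO (SD, n = 3 each).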

How the results depend on the processing

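Alternatives with other library sizes, classes of overlap or without both libraries that hold Y-linked counts were chosen after the data were examined. The count of called genes was 0 with RLE, upper quartile, the exact test (lowest adjusted p 0.0894), limma-voom, DESeq2, the looser adjusted p of 0.1, a minimum fold, both other library sizes and both overlap classes. It was 6 with no filter (5 higher: Erdr1, Gtf3c2, Inf2, E130310I04Rik and Gm15441; Rn45s lower), 1 (Erdr1) with a CPM filter and 1 (Erdr1) without both libraries that hold Y-linked counts, and 0 to 1 leaving out each library; the cause was not tested. The number of genes with unadjusted p under 0.05 was 108 (DESeq2) to 638 (no filter). The share of them that was higher in KO, 34.2%, was 17.5% with scaling to all uniquely aligned reads, 47.2% with DESeq2, 44.2% with the CPM filter and 42.8% with no filter. The replicate block called 0 genes, 287 at an unadjusted p under 0.05, and 2 lists. The deviations of samples with equal numbers correlated across tested genes at 0.143, 0.0795 and 0.122. The labels name no pairing, and the numbers were not taken as pairs in the main test. Yet every sample correlated best with its own number, at 0.528, 0.474 and 0.657 in 1007 genes with a mean count of 100 or more. In those genes, samples with different numbers correlated at -0.434 to 0.0197. The pairs of equal number also had the lowest chi-square per degree of freedom (3.06, 2.34 and 2.56). The libraries thus shared a structure by number that the main test leaves out, and the labels do not give its source. In a test chosen after the result was seen, sex alone was taken to give a correlation of 0.1 or less without the replicates 3. There WT 1 minus WT 2 correlated with KO 1 minus KO 2 at 0.106 across genes (bootstrap 0.0746 to 0.137, which includes that bound). In those 1007 genes the correlation was 0.404 (0.318 to 0.481), so sex alone did not account for the structure in them. The bootstrap resamples genes, not animals. Stim1 kept its direction, from -2.32 to -0.79 leaving out each library. Passing lists numbered 2 with RLE, 3 with either other library size, 0 with an estimated correlation, fry, the CPM filter, no opposite overlap or without both libraries with Y-linked counts, and 0 to 4 leaving out each library (0 without KO replicate 3, 4 without KO replicate 2, 1 without WT replicate 1 or 2); the cause was not tested. Of 1044 values of named genes 1017 kept side and direction and 22 reversed, none of them called; the other 5 passed (Erdr1 in 4 settings and Gtf3c2 with no filter). Without both libraries with Y-linked counts these were Gfap 0.14, Apoe -0.13, Trf 0.028, Cnp -0.29 and Gpr17 -0.10; Tsix was 0.35 with limma-voom, and Apoe -0.016 with scaling to all aligned reads. Leaving out each library, Apoe ranged from -0.14 to 0.28, Cnp -0.26 to 0.41, Gpr17 -0.061 to 0.33, Xist -0.73 to 0.59, Tsix -0.66 to 0.51, Nefh -0.49 to 0.040, Ptgds -0.35 to 0.55 and Prlr -0.43 to 0.61. Of 359 list results 305 kept side and direction, 16 lost a call, 6 gained one and 32 reversed. The test direction reversed among genes with no opposite overlap for store-operated entry (median 0.048), the unfolded protein response (0.12), glial reactivity (0.087), cholesterol synthesis (0.11) and granule cells (0.063). It did for calcium channels with fry (-0.050), the CPM filter (-0.076) and the block (-0.045), histone enzymes with fry (-0.0074) and the block (-0.0063), the unfolded protein response with RLE (0.030), cholesterol synthesis with the block (0.025), granule cells with the CPM filter (0.038), and, without both libraries with Y-linked counts, cholesterol synthesis (0.13), granule cells (0.12) and oligodendrocytes (0.031). Leaving out each library, medians ranged from -0.062 to 0.11 for calcium channels, -0.018 to 0.080 for the unfolded protein response, -0.13 to 0.0028 for ribosomal proteins, -0.17 to 0.21 for glial reactivity, -0.10 to 0.12 for histone enzymes, -0.14 to 0.077 for cholesterol synthesis, -0.18 to 0.046 for granule cells and -0.18 to 0.075 for oligodendrocytes. Depth limits single genes, since 2014 of 5320 tested genes had a mean count under 20.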

Other observations

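Several of the genes with the most counts lie opposite Purkinje or synaptic genes; the examples were chosen after their values were seen, and others, such as Stx18 (8145) and Fchsd1 (4470), have partners on none of the lists. Pet100 held 20379 counts per library on average and lies opposite Pcp2, the Purkinje cell protein, which held 61.2. Ddx49 held 10604 opposite Homer3 with 344, Chtf18 4462 opposite Gng13 with 51.2, Grin1os 7633 opposite Grin1 with 26.2, and Nkx6-2 3410 opposite Inpp5a with 40.7. Between genotypes none of these passed, with log2 fold changes of -0.075 (SE 0.16) for Pet100, -0.00097 (SE 0.17) for Ddx49, 0.14 (SE 0.19) for Chtf18, 0.071 (SE 0.11) for Grin1os and 0.030 (SE 0.17) for Nkx6-2. Among abundant genes with an opposite partner, 9130019P16Rik, opposite Chn2, stood at 0.41 (SE 0.14) and Ctsa, opposite Pltp, at 0.34 (SE 0.15), with edgeR adjusted p of 0.917 and 0.987. Of 13 lists redrawn through opposite partners, with 3 to 10 genes each, 0 passed camera (lowest adjusted p 0.854). So few genes cannot speak for the full lists. Inf2 had 0 counts in the 3 WT libraries and 7, 2 and 10 in KO.

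The lower presynaptic and glutamate receptor lists were weighed with tests written before the result was seen, except the test of glia. If the listed transcripts themselves were lower and were read through opposite genes, those genes should be lower. Yet the 9 tested ones had a median log2 fold change of 0.048 (bootstrap 95% interval -0.040 to 0.073), above the bound set in advance at -0.096. None of the 9 lies opposite Vamp1, Syt11, Dlg4 or Gria1, and the interval resamples genes, not animals. The test therefore covers these 9 partners and cannot decide for the lists. A lower background in the knockout libraries may account for the lists. Genes with no opposite overlap had a median of -0.057 (-0.070 to -0.042, resampling genes, not animals), which is less than the size set in advance. By library, these genes held 22.97% ± 1.602 of gene counts in WT and 21.94% ± 1.302 in KO (SD, n = 3 each). An exact permutation test gave p = 0.5, so the libraries do not show a lower share beyond their spread. Among genes with no opposite overlap, 25 and 15 list members were left. Their unadjusted camera p was 0.0276 for the presynaptic and 0.0603 for the glutamate receptor list. When such genes were normalised alone it was 0.0494 and 0.0655 (medians -0.12 and -0.11, adjusted p 0.546 for both). A lower background therefore stays open. Less neuronal RNA would raise glial markers, yet the 19 astrocyte and Bergmann glia markers had a median of -0.28 (-0.39 to 0.018), an interval that reaches 0 and leaves this open too, beside loss of STIM1.

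The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For called genes the real split gave 0, which each of the 10 splits reaches by necessity, and the highest other 10; for genes at an unadjusted p under 0.05 the real split gave 246 and the highest other 384, with 6 splits as large; for lists the real split gave 2 and the highest other 2, with 2 splits as large. Every split with more than 246 genes put libraries of an equal replicate number on the same side. The other splits that part all equal numbers gave 219, 195 and 146 genes at an unadjusted p under 0.05 and 0 lists, fewer than the real split. They gave 1, 1 and 0 called genes, where the real split gave 0. Such splits are too few for a test. The split with 10 genes set WT replicate 1, KO replicate 1 and KO replicate 3 against the rest, which may point to a structure of the samples other than genotype. What that split reflects was not tested. A hypothesis written before its test, that DNA of a donor strain around Stim1 may add differences, was not settled: 3 of 48 tested genes within 10 megabases had an unadjusted p under 0.05 (6.25%), against 4.61% of the other genes (one-sided Fisher exact p = 0.384).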
